A study of Mus musculus with 12 samples.

How the data were processed

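Total RNA from E14 mESCs and from EpiLCs derived from them was sequenced in 12 libraries, 3 for each of 4 groups (WT or mutant EPOP, mESC or EpiLC). Per the labels' protocols, mESCs grew in 2i/LIF on gelatin, EpiLCs were made on fibronectin with activin A and bFGF, RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra II kit. Groups were taken from the genotype and cell type labels. The count table names its non-WT columns with a code that the labels do not spell out; these were taken as the mutant because the labels hold only WT and mutant EPOP, and the directions of mutant against WT and of the difference of effects rest on that. Both genotypes re-express EPOP, and parental or knockout cells were not analysed here. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

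The deposited counts are raw counts per gene. Per the submitters' processing notes, the tools included FastQC 0.11.2, STAR 2.5.3a, featureCounts of Subread and edgeR 3.18.1, with the mm10 build. Whether counting used strand is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. The authors' deposited CPM columns, a score scaled to effective library sizes, were compared with the counts only. The authors' deposited TPM columns, scaled by the authors to equal column sums, were not used in tests. The authors' deposited log2 fold changes and p-values were used only to count and compare calls: across genes the deposited log2 fold changes correlated with those computed here at r = 1.0000 in each of 3 comparisons. The authors' comparisons used here did not include mutant against WT in mESCs, so those calls were not set against the authors' own.

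The table held 19656 features. Of these, 26 carry spreadsheet dates in place of symbols and hold 0.182 to 0.212% of a library's counts, and they were left out of library sizes and tests. Symbols were matched to GENCODE M21 (GRCm38), 18550 directly and 768 through a synonym, and 312 were unmatched. Replicate pairs differed by more than sampling noise (chi-square per degree of freedom 1.91 to 3.00), so no library was a copy of another.

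Genes were kept with filterByExpr, scaled by TMM (factors 0.98 to 1.01) and tested with the edgeR 4.0.16 quasi-likelihood test (glmQLFit, robust, and glmQLFTest) in R 4.3.3, with 1 fit to all 12 libraries and 8 residual degrees of freedom. The biological coefficient of variation was 4.57%. Adjusted p is by Benjamini-Hochberg over 13879 genes, with calls at 0.05. The 5 comparisons were mutant against WT in each state, the difference of these effects, and EpiLC against mESC in each genotype. CPM are from effective library sizes. A fold against a group with no count was computed against a floor of 3 counts over the group, which covers counting error only. Exon overlaps and transcript GC content and length came from the annotation with bedtools 2.31.1, Python 3.11.15 and pandas 2.3.3.

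In all, 27 gene lists were written from general knowledge before the data were examined. Of these 26 had at least 5 tested members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. The list of mitochondrially encoded genes had no member in the table used. fry tests whether a list's genes move on balance one way, without comparing them with other genes.

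Named genes were chosen by a rule fixed before the data were examined. It takes Epop; per comparison the 6 genes with the largest rise and the 6 with the largest fall (4 each for the difference of effects) among called genes with a mean of at least 2 CPM, groups that do not overlap and a symbol that is not a predicted or clone name; the 3 called members of each list with the largest change (the 1 largest for EpiLCs against mESCs in mutant cells); and 7 pluripotency and epiblast genes for the state comparisons. For the difference of effects, groups may overlap. Genes are printed in part only, 1 gene that the rule gives is not reported here, and genes outside this rule are named as chosen after their values were seen. Values of Esrrb and Cdkn1c in mESCs are given beside their difference of effects.

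The steps were tested on simulated data drawn from these libraries, with 200 genes changed. For mutant against WT in mESCs, 74.6% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 97.0% of those changed 4-fold were recovered, and 3.83% of calls were of unchanged genes. In EpiLCs the shares were 80.6%, 80.6% and 98.5%, with 2.81% of calls false. For the difference of effects they were 55.2%, 82.1% and 93.9%, with 5.52% false.

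Alternatives were relative log expression size factors, DESeq2 1.42.0, limma-voom, other filters on low counts, a fit to the compared groups only, a block on the replicate number, a 2-fold threshold, fry, an estimated correlation, and each library left out in turn.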

Results

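RNA was sequenced in mouse embryonic stem cells (mESCs) of the E14 line and in epiblast-like cells (EpiLCs) derived from them. Both states were sampled from cells re-expressing either wild-type (WT) EPOP or a mutant EPOP, with 3 libraries in each of 4 groups. EPOP is a protein associated with Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3 at repressed genes. The series asks how EPOP limits where the PRC2.1 form of the complex binds. The RNA comparisons address which transcripts differ between cells with the WT and the mutant protein. The mESCs were kept in 2i/LIF medium, which holds cells in the naive state, and EpiLCs were made with activin A and bFGF, which move cells towards the early post-implantation epiblast. The 12 libraries held 7714164 to 10652151 counts in named genes, and 13879 genes were tested. The first principal component, with 79.5% of the variance, separated the states, and the second, with 6.45%, separated WT from mutant cells.

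Epop mRNA, listed under the symbol E130012A19Rik, differed between the proteins by less than the spread between replicates. It stood at 472.9 ± 10.8 CPM (read counts scaled to library size; SD, n = 3) in WT and 468.7 ± 6.2 in mutant mESCs, and at 208.8 ± 3.3 in WT and 206.6 ± 9.4 in mutant EpiLCs. The gene lies on chromosome 11 from 97627389 to 97629702 in GRCm38. The edgeR adjusted p for mutant against WT was 0.877 in mESCs and 0.867 in EpiLCs, so the transcript level does not check which libraries carry the mutant. The nature of the mutation is not given in the sources used here.

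In mESCs, the mutant cells had lower levels of 2-cell-like, germline, Hox and other Polycomb target transcription factor genes. Hoxd13, a posterior patterning gene, fell from 10.6 ± 3.1 to 1.06 ± 0.38 CPM, and Hoxd9 fell from 7.66 ± 0.18 to 0.679 ± 0.42 CPM. Sohlh2, a germ cell transcription factor, fell from 63.5 ± 4.0 to 18.6 ± 1.4 CPM. In the other direction, Lin28a, an RNA-binding pluripotency factor, rose from 55.5 ± 4.7 to 156.6 ± 3.9 CPM. Gli1, a Hedgehog pathway transcription factor, rose from 13.6 ± 3.6 to 41.8 ± 4.6 CPM, although its exons overlap those of Arhgap9.

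Of the 13879 genes, 2574 were called in mESCs by the edgeR quasi-likelihood test at an adjusted p under 0.05, with 1166 higher and 1408 lower in mutant cells. Among calls of at least 2-fold, 72 were higher and 462 lower, so 86.5% were lower. Among called genes with a mean of at least 2 CPM and separate groups, Ccdc126 had the largest rise, from 5.89 ± 1.1 to 31.0 ± 2.7 CPM, a log2 fold change of 2.38 ± 0.14 (SE; edgeR adjusted p = 2.17e-31). Phlda2, an imprinted growth regulator, rose from 7.91 ± 2.2 to 29.6 ± 2.0 CPM. Among the same genes Xlr3a had the largest fall, from 4.82 ± 0.73 to 0.218 ± 0.0083 CPM, but near-identical copies of Xlr3 genes can share reads.

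Of 15 tested 2-cell-like genes, which mark a rare totipotent-like state of mESC cultures, 14 fell and none rose. The count was also 14 when adjusted over the list alone (camera adjusted p = 7.17e-18). Zscan4e fell from 11.1 ± 1.1 to 1.24 ± 0.53 CPM, and Zscan4b from 5.08 ± 1.5 to 0.507 ± 0.056 CPM. Members of the Zscan4 and Usp17l families are near-identical, so the split of reads among them is uncertain. Of 28 germline genes, 16 fell and none rose, with the same 16 when adjusted over the list alone (camera adjusted p = 3.64e-09). Taf7l fell from 5.21 ± 1.4 to 1.27 ± 0.50 CPM.

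Of 91 tested Polycomb target transcription factors, 31 fell and 6 rose, against 37 and 6 when adjusted over the list alone (camera adjusted p = 1.31e-05). Sox1, a neural transcription factor, fell by 1.33 on the log2 scale (edgeR adjusted p = 7.95e-17), and Twist1, a mesenchymal one, fell from 5.58 ± 0.80 to 1.21 ± 0.79 CPM. Of 28 Hox genes, 10 fell and 1 rose, against 11 and 2 when adjusted over the list alone (camera adjusted p = 0.00104). Hoxa9 had no count in the 3 mutant libraries and was at least 8.48-fold lower, with the floor set at 3 counts over the group. Of 20 Polycomb target signalling genes, 3 fell and 1 rose, against 4 and 1 adjusted over the list alone, and the list was not called (camera adjusted p = 0.271).

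Imprinted genes, which are expressed from 1 parental allele, fell as a list, with 15 of 33 lower and 2 higher, or 16 and 3 when adjusted over the list alone (camera adjusted p = 1.31e-05). Peg13 fell by 4.47 on the log2 scale (edgeR adjusted p = 2.05e-09), while Slc22a18 rose from 1.24 ± 0.72 to 4.54 ± 0.41 CPM. Of 20 integrated stress response genes, 7 fell and none rose, also 7 adjusted over the list alone (camera adjusted p = 0.00232), and Ddit4 fell from 51.7 ± 1.1 to 32.9 ± 4.3 CPM. General pluripotency genes rose, with 6 of 14 higher and none lower under either adjustment, including adjusted over the list alone (camera adjusted p = 0.00124). ERK target genes rose, with 8 of 24 higher and 1 lower, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00232). Myc rose from 15.3 ± 0.80 to 34.7 ± 2.1 CPM, and Spry4, a feedback inhibitor of the pathway, from 9.59 ± 2.3 to 20.1 ± 3.9 CPM.

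The 8 lists above that were called in mESCs were also called with an estimated correlation, with adjusted p of 0.00236 for 2-cell-like and germline genes, 0.00509 for Polycomb target transcription factors, 0.00622 for imprinted genes, 0.0157 for Hox genes, 0.0227 for the stress response and ERK targets and 0.0481 for general pluripotency. With an estimated correlation, the adjusted p of general pluripotency was 0.0585, 0.0734 and 0.0653 without mutant mESC replicates 1, 2 and 3, and 0.0709 with relative log expression size factors and all libraries. A further 6 lists passed only with the preset correlation. Fibroblast and feeder markers had 4 of 11 members lower, 5 adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.0805 with an estimated correlation), and 7 members were not called. Oxidative phosphorylation genes had 6 of 25 higher under both adjustments (0.013, and adjusted p = 0.18 with an estimated correlation), and the camera value was 0.0517 without WT mESC replicate 1. Cholesterol synthesis genes had 6 of 20 lower, or 9 lower and 1 higher adjusted over the list alone (0.0198, and adjusted p = 0.18 with an estimated correlation), and the camera value was 0.0593 without WT mESC replicate 1. Neuroectoderm genes had 6 of 18 lower and 1 higher, or 9 and 2 adjusted over the list alone (0.023, and adjusted p = 0.0709 with an estimated correlation). Glycolysis genes had 8 of 21 lower and 1 higher, or 8 and 2 adjusted over the list alone (0.0321, and adjusted p = 0.174 with an estimated correlation), with camera values of 0.0701, 0.0754 and 0.0958 without WT replicate 1, mutant replicate 1 and mutant replicate 2. Endoderm genes had 6 of 22 lower and 2 higher, or 7 and 3 adjusted over the list alone (0.0418, and adjusted p = 0.122 with an estimated correlation), with camera values of 0.0593 and 0.0504 without WT replicate 1 and mutant replicate 3.

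Naive pluripotency genes were not called as a list in mESCs, with 6 of 25 lower and 3 higher, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.801). Esrrb had a log2 fold change of -0.02 ± 0.04 (SE; edgeR adjusted p = 0.732). Core and accessory PRC2 subunits had 3 of 13 higher and 2 lower, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.616). PRC1 subunits had 4 of 21 lower and 1 higher, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.141).

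**Figure D1:**
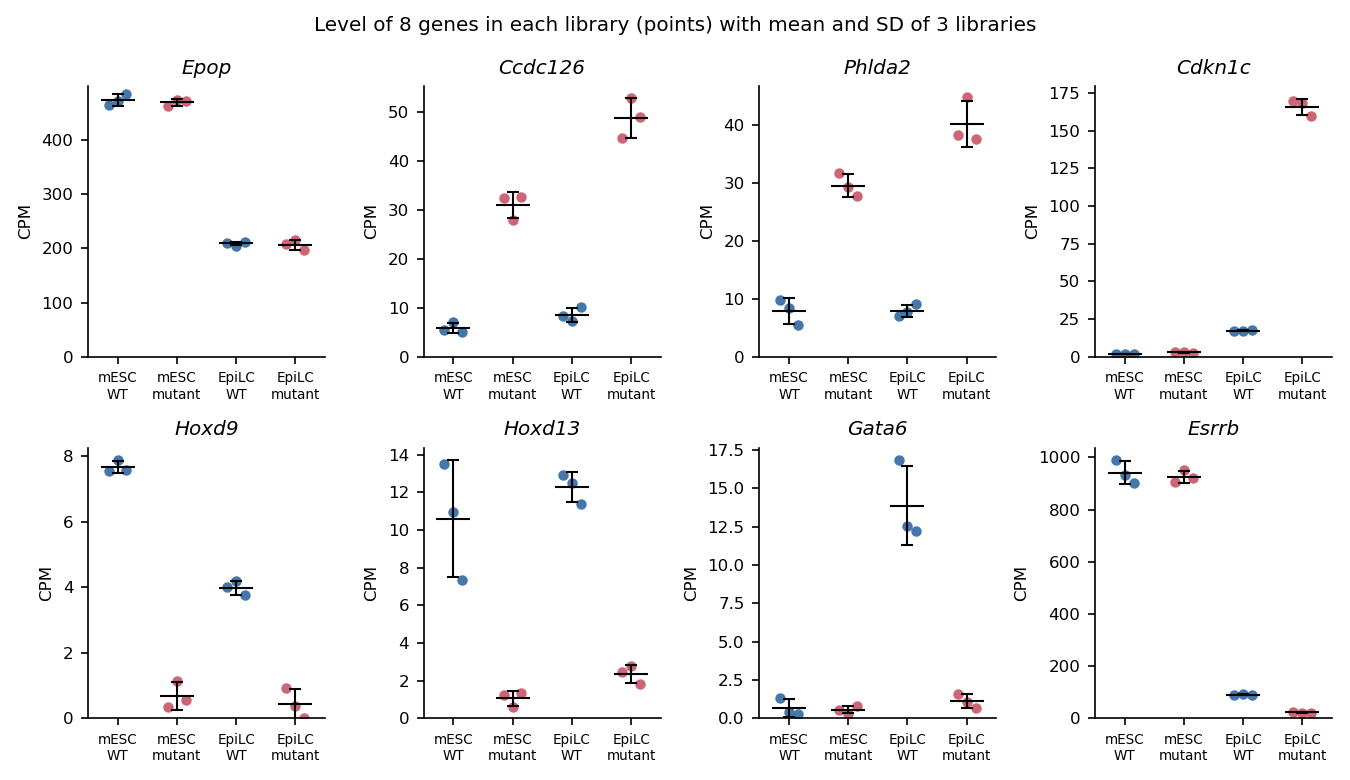
Level of 8 genes in CPM (read counts scaled to library size, vertical axes from 0) in each of the 12 libraries, with WT in blue, mutant in red, and the mean ± SD of 3 libraries in black. Epop stood at similar levels with either protein, Hoxd9 and Hoxd13 were lower in mutant cells of both states, and Esrrb and Gata6 were lower in mutant EpiLCs.

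In EpiLCs, naive pluripotency genes were lower in mutant than in WT cells, together with 2-cell-like, germline, stress response and endoderm genes. Esrrb, a naive pluripotency transcription factor, fell from 90.6 ± 3.0 to 22.4 ± 2.8 CPM, and Tet2, an enzyme that oxidises methylated cytosine, fell from 145.8 ± 4.6 to 78.8 ± 7.6 CPM. Gata6, an endoderm transcription factor, fell from 13.9 ± 2.6 to 1.13 ± 0.45 CPM, although its exons overlap those of 1010001N08Rik. Cdkn1c, an imprinted inhibitor of the cell cycle, rose from 17.4 ± 0.52 to 165.8 ± 5.4 CPM. H19, an imprinted non-coding RNA, was at 7.61 ± 0.62 CPM in WT EpiLCs and had no count in the 3 mutant libraries, at least 70.2-fold lower with the floor of 3 counts over the group.

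The edgeR test called 2198 genes in EpiLCs, 974 higher and 1224 lower in mutant cells, and among calls of at least 2-fold 45 were higher and 202 lower. Cdkn1c had a log2 fold change of 3.25 ± 0.08 (SE; edgeR adjusted p = 6.99e-68), and Gata6 one of -3.57 ± 0.30 (edgeR adjusted p = 9.36e-20). The authors' deposited table for this comparison called 2420 genes, 1104 higher and 1316 lower, of which 2062 were among the 2198. Fgf8, a signalling ligand of the primitive streak, rose from 2.70 ± 0.53 to 8.76 ± 1.3 CPM, and Bcl11a from 6.73 ± 0.55 to 19.3 ± 1.0 CPM. Ccdc126 and Phlda2 rose as they had in mESCs, to 48.8 ± 4.1 and 40.3 ± 4.0 CPM.

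Of 25 naive pluripotency genes, 19 fell and 1 rose in mutant EpiLCs, under both adjustments, including adjusted over the list alone (camera adjusted p = 8.06e-16). Tcl1 fell from 2.58 ± 0.58 to 0.663 ± 0.16 CPM, and Gbx2, chosen after its values were seen, was the member that rose, from 119.4 ± 2.3 to 203.3 ± 1.7 CPM. Of 20 integrated stress response genes, 13 fell and 1 rose, or 16 and 1 adjusted over the list alone (camera adjusted p = 8.85e-09), and Chac1 fell from 81.9 ± 4.6 to 35.7 ± 3.7 CPM. Of 15 2-cell-like genes, 11 fell and none rose, or 14 and none adjusted over the list alone (camera adjusted p = 1.50e-13). Of 28 germline genes, 13 fell and none rose, or 14 and none adjusted over the list alone (camera adjusted p = 6.43e-06).

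Of 22 endoderm genes, 8 fell and 1 rose, or 9 and 1 adjusted over the list alone (camera adjusted p = 3.23e-04), and Sox17 fell from 2.22 ± 0.61 to 0.374 ± 0.27 CPM. Of 91 Polycomb target transcription factors, 19 fell and 5 rose, or 21 and 5 adjusted over the list alone (camera adjusted p = 3.60e-04). These 6 lists were also called with an estimated correlation, with adjusted p of 3.46e-04 for naive genes, 0.00206 for the stress response, 0.00236 for 2-cell-like genes, 0.00631 for germline genes, 0.0168 for endoderm and 0.00989 for Polycomb target transcription factors. Hox genes were not called, with 11 of 28 higher and 4 lower, or 12 and 5 adjusted over the list alone (camera adjusted p = 0.336), and their median log2 fold change of 0.25 differed in sign from their mean of -0.16. Hoxd13 fell from 12.3 ± 0.79 to 2.36 ± 0.49 CPM.

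PRC2 subunits had 5 of 13 members lower and none higher under both adjustments, including adjusted over the list alone (camera adjusted p = 0.0277, and adjusted p = 0.0943 with an estimated correlation, while without mutant EpiLC replicate 1 the camera value was 0.113). Suz12, a core subunit, fell from 272.7 ± 11.9 to 220.8 ± 4.0 CPM. Genes for DNA methylation enzymes had 6 of 14 lower and 2 higher under both adjustments, including adjusted over the list alone (camera adjusted p = 0.0217, and adjusted p = 0.125 with an estimated correlation, while without WT EpiLC replicate 1 the camera value was 0.061). Zfp57, which protects imprinted methylation, fell from 198.1 ± 6.6 to 110.0 ± 6.7 CPM, and Tet1 fell from 634.2 ± 41.9 to 421.8 ± 29.3 CPM. Oxidative phosphorylation genes had 4 of 25 higher under both adjustments (camera adjusted p = 0.0126, and adjusted p = 0.199 with an estimated correlation). Formative and primed epiblast genes had 12 of 29 higher and 6 lower, or 16 and 7 adjusted over the list alone, and were not called (camera adjusted p = 0.149). Pim2 rose from 53.1 ± 1.8 to 127.4 ± 3.0 CPM and Lef1, a WNT pathway transcription factor, from 151.7 ± 6.4 to 224.2 ± 10 CPM.

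**Figure D2:**
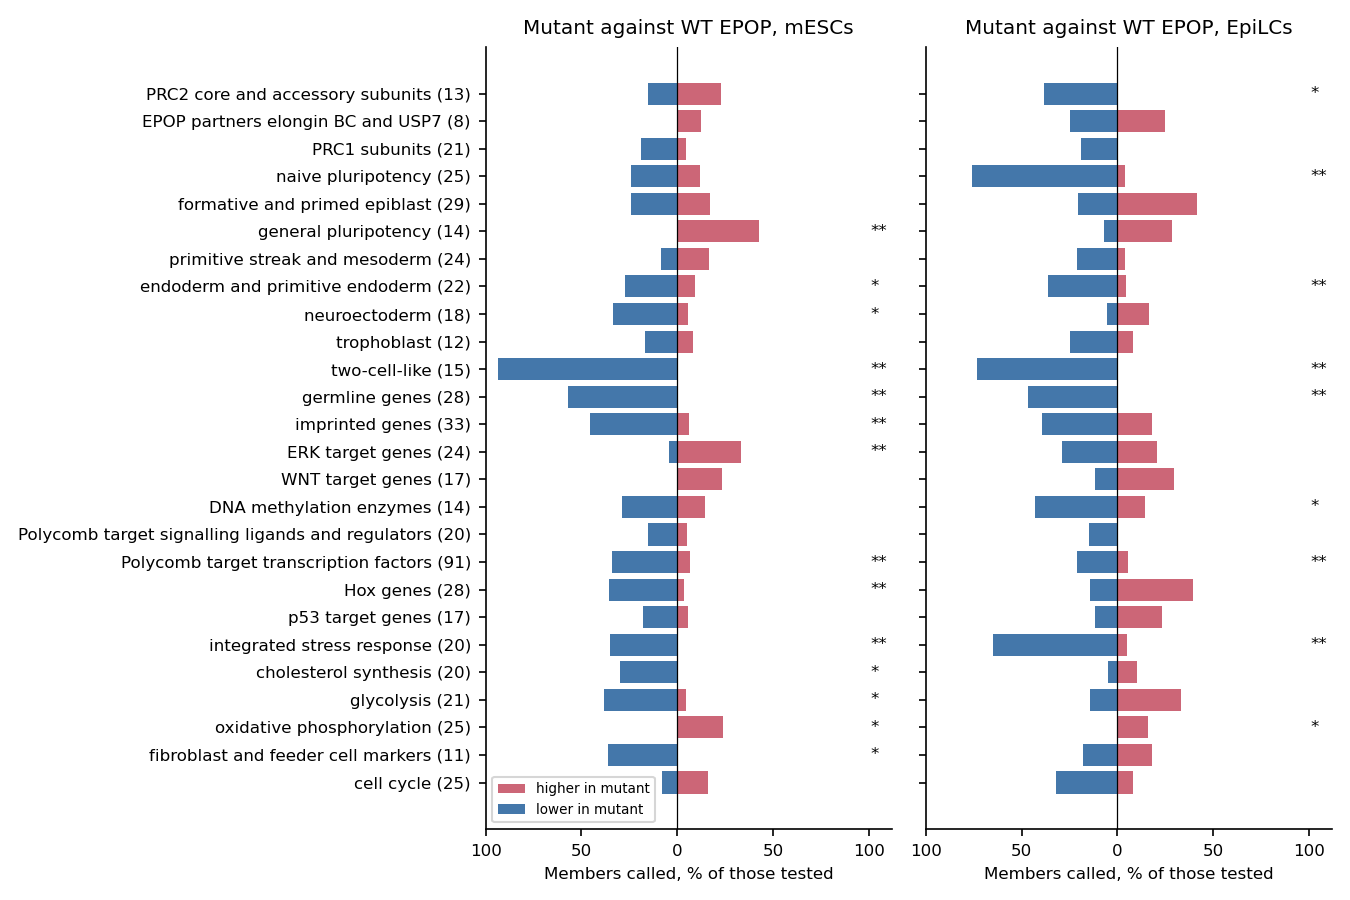
Percent of tested members of each gene list (number tested in brackets) called higher (red, to the right of 0) or lower (blue, to the left of 0) in mutant than in WT cells. One asterisk marks lists called by camera with the preset correlation and a double asterisk those also called with an estimated one, and naive pluripotency genes carry the double mark in EpiLCs only.

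In mESCs and EpiLCs respectively, the camera adjusted p of lists called in neither state was 0.932 and 0.0831 for primitive streak and mesoderm genes, 0.477 and 0.556 for trophoblast genes, 0.477 and 0.526 for WNT targets, 0.971 and 0.653 for p53 targets, 0.5 and 0.0831 for cell cycle genes and 0.514 and 0.653 for EPOP partners. Formative genes, also called in neither state, had a value of 0.507 in mESCs, and DNA methylation enzymes had 0.877 there. Lists not called in EpiLCs, some of them called in mESCs, had values of 0.253 for general pluripotency, 0.64 for ERK targets, 0.683 for neuroectoderm, 0.319 for PRC1 subunits, 0.149 for Polycomb target signalling genes, 0.763 for cholesterol synthesis, 0.577 for glycolysis and 0.583 for fibroblast markers. Imprinted genes in EpiLCs had 13 of 33 lower and 6 higher, or 13 and 8 adjusted over the list alone (camera adjusted p = 0.0831, and 0.0498 without WT EpiLC replicate 2). Among these uncalled lists the median, the mean and the test differed in sign for PRC2 subunits, mesoderm, trophoblast and p53 target genes in mESCs and for neuroectoderm genes in EpiLCs.

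The effect of the mutant differed between the states for a set of genes that included most naive pluripotency members. The difference was tested as an interaction, the mutant effect in EpiLCs minus that in mESCs. Esrrb had a difference of -1.98 ± 0.08 log2 (SE; edgeR adjusted p = 3.16e-48), since it was at similar levels in both kinds of mESC and lower in mutant EpiLCs. Khdc3, an oocyte and early embryo gene, had a difference of -2.55 ± 0.27, with 5.29 ± 0.21 CPM in WT and 1.07 ± 0.20 CPM in mutant EpiLCs. Tbx3 had a difference of -1.61 ± 0.14, and Gata6 one of -3.29 ± 0.70. Cdkn1c differed the other way, by 2.63 ± 0.29, with 1.97 ± 0.21 CPM in WT and 3.01 ± 0.38 CPM in mutant mESCs.

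In this test 1351 genes were called, 650 with a positive and 701 with a negative difference. Naive pluripotency genes had 16 of 25 members with a negative difference and none with a positive one, or 17 and none adjusted over the list alone (camera adjusted p = 4.56e-14, and adjusted p = 5.36e-04 with an estimated correlation). Hox genes had 6 of 28 positive and none negative under both adjustments, including adjusted over the list alone (1.39e-04, and adjusted p = 0.0163 with an estimated correlation). The 2-cell-like genes had 5 of 15 positive and none negative, or 10 and none adjusted over the list alone (2.15e-05, and adjusted p = 0.0443 with an estimated correlation), so their fall was smaller in EpiLCs. The 2-cell-like call with an estimated correlation was lost without 9 of the 12 libraries, with adjusted p from 0.0578 to 0.0901. A further 11 lists passed only with the preset correlation and had adjusted p of 0.0632 or more with an estimated correlation. Of the 14 lists called with the preset correlation, 8 were called without mutant mESC replicate 2 and 9 without WT EpiLC replicate 2.

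Calls in the 2 states overlapped in direction. There were 275 genes higher and 409 lower in mutant cells of both states, where independent lists would share 81.8 and 124.2. Opposite calls were fewer, with 66 genes higher in mESCs and lower in EpiLCs against 102.8 for independent lists, and 60 the other way against 98.8. The comparisons share no library. Across 13879 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.28 and a Spearman rho of 0.26.

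Genes of the mESC to EpiLC step also differed between mutant and WT cells. Of 1673 genes called higher in EpiLCs in both genotypes, with a mean change of at least 2-fold, 395 were lower and 78 higher in mutant than in WT mESCs, while 230 were higher and 127 lower in mutant than in WT EpiLCs. Of 1265 genes called lower in the same way, 252 were lower and 30 higher in mutant EpiLCs, against 153 lower and 162 higher in mutant mESCs. Across 13879 genes, the mutant effect had a Pearson r of -0.26 (Spearman rho -0.21) with the mean change from mESC to EpiLC when taken in mESCs, and of 0.22 (rho 0.13) when taken in EpiLCs. In 20 simulated data sets without a mutant effect these r lay from -0.032 to 0.030 and from -0.030 to 0.035. The mean change includes the mutant libraries, so a mutant effect unrelated to the step can itself give a negative r in mESCs and a positive one in EpiLCs. Simulations without a mutant effect do not cover that. The r, and the counts of genes chosen by the mean change, thus do not show that the mutant acts on the step.

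**Figure D3:**
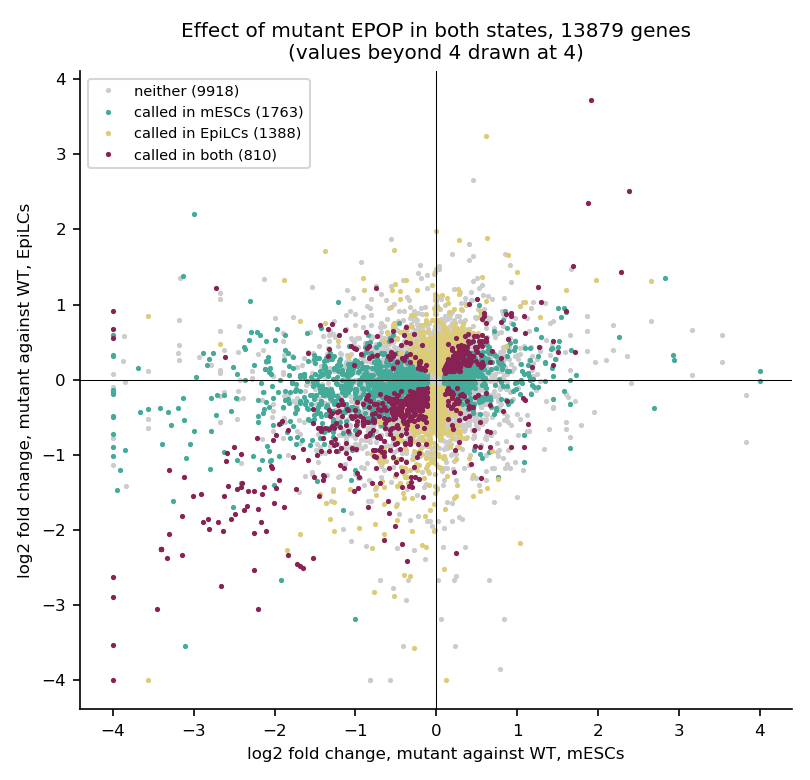
Log2 fold change of mutant against WT in mESCs (horizontal axis) and in EpiLCs (vertical axis), 1 point per gene for 13879 genes, coloured by where the gene was called, with values beyond 4 drawn at 4. The 409 genes lower in both states lie at the lower left and the 275 higher in both at the upper right.

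The step from mESC to EpiLC gave more calls than the mutant, with lower naive and higher formative pluripotency genes in EpiLCs. In WT cells Nanog fell from 1155.9 ± 32.0 to 233.6 ± 8.5 CPM, and Zfp42, also called Rex1, from 866.9 ± 12.8 to 129.1 ± 4.9 CPM. In mutant cells Zfp42 fell from 893.0 ± 10.5 to 64.0 ± 5.6 CPM. Lef1 rose in WT cells from 1.18 ± 0.43 to 151.7 ± 6.4 CPM, and Dnmt3a, a de novo DNA methyltransferase, from 72.8 ± 5.3 to 704.1 ± 26.2 CPM, although Dnmt3a shares exon sequence with Dnmt3aos. Pou5f1 stayed high, at 1231.7 ± 31.5 CPM in WT mESCs and 848.1 ± 29.9 CPM in WT EpiLCs. Epop fell in both genotypes by 1.18 on the log2 scale.

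The edgeR test called 8697 genes in WT cells, 4397 higher and 4300 lower in EpiLCs, and 9155 in mutant cells, 4631 higher and 4524 lower. The authors' deposited table called 9353 and 9950, of which 8510 and 8969 were shared. Naive genes had 21 of 25 members lower and 3 higher in both genotypes, with the same counts adjusted over the list alone (camera adjusted p = 2.20e-09 in WT and 4.01e-10 in mutant cells). Formative and primed genes had 26 of 29 higher in both genotypes, with 2 lower in WT and 1 in mutant cells, or 26 higher with 3 and 1 lower adjusted over the list alone (2.01e-12 and 1.05e-11). Hox genes had 18 of 28 higher and 6 lower in WT and 19 higher and 5 lower in mutant cells, the same adjusted over the list alone (0.00219 and 3.08e-04), and imprinted genes had 20 of 33 higher and 5 lower in both, or 20 and 22 higher and 5 lower adjusted over the list alone (0.00216 and 7.21e-04). Hoxb1 had no count in WT mESCs and was at least 135.2-fold higher in WT EpiLCs.

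Oxidative phosphorylation genes had 24 of 25 lower in WT EpiLCs and 22 in mutant EpiLCs, with none higher, the same adjusted over the list alone (1.05e-06 and 1.16e-05), with adjusted p of 0.0447 and 0.0698 with an estimated correlation (0.0812, 0.0888 and 0.0547 in WT cells without WT EpiLC replicates 1, 2 and 3). Cholesterol synthesis genes had 16 of 20 higher in both genotypes, with 2 lower in WT and 1 in mutant cells, under both adjustments (0.00277 and 7.21e-04), with adjusted p of 0.186 and 0.108 with an estimated correlation. In mutant cells, 2-cell-like genes had 9 of 15 higher and 1 lower (0.00551, and adjusted p = 0.114 with an estimated correlation), germline genes 17 of 28 higher and 5 lower (0.017, and adjusted p = 0.0877 with an estimated correlation) and fibroblast markers 7 of 11 higher and 2 lower (0.041, and adjusted p = 0.136 with an estimated correlation, while the camera value was 0.0539 without mutant mESC replicate 1 and 0.0579 without mutant EpiLC replicate 2), each with the same count adjusted over the list alone. With all libraries and no block, the naive, formative, Hox and imprinted lists were also called with an estimated correlation in both genotypes, with adjusted p from 0.00198 to 0.0326. Left-out libraries ended some of these calls, as imprinted genes stood at 0.0561 and 0.0547 without WT EpiLC replicates 1 and 3 and at 0.0661 without mutant EpiLC replicate 3, and Hox genes at 0.0503 without WT EpiLC replicate 3.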

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

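The tests for cells of another state, for a lower level already present in mESCs and for the swapped genotype, and the added limits on cell shares, were chosen after the result was seen. The trend and split tests were chosen before. The results of the next paragraph stand out because the effect of the mutant differed between mESCs and EpiLCs in a test of the difference itself.

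The difference passed for 1351 genes. By camera adjusted p, the difference was negative for naive pluripotency genes (4.56e-14) and positive for 2-cell-like genes (2.15e-05) and Hox genes (1.39e-04). The median log2 fold change of naive genes was -0.02 in mESCs and -0.65 in EpiLCs. That of 2-cell-like genes was -2.70 in mESCs and -1.55 in EpiLCs, a smaller fall in EpiLCs. By the naming rule, the 4 most positive differences were those of Hoxa9 (edgeR adjusted p = 1.00e-06), Cnr1 (2.32e-04), Fat3 (0.00671) and Fgf5 (0.00994). These 4 genes had no count in mutant mESCs, so their fitted fold changes give no size. Among called genes with a mean of at least 2 CPM, the 4 most negative differences on the log2 scale were Gata6 at -3.29, Inhbb at -2.60, Khdc3 at -2.55 and Prdm14 at -2.10. The call for Prdm14 (adjusted p = 0.0329) was lost with DESeq2 (0.0642) and limma-voom (0.126), and without mutant mESC replicate 1 (0.0502), WT EpiLC replicate 2 (0.344), mutant EpiLC replicate 1 (0.0606) and mutant EpiLC replicate 3 (0.17).

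Naive pluripotency genes were lower in mutant than in WT EpiLCs, with 19 of 25 called. A smooth trend with GC content, transcript length or expression was argued against, since the median log2 fold change was -0.64 after its removal and -0.65 before. A lower level already present in mutant mESCs, as the whole cause, was argued against, since the median log2 fold change of all 25 members there was -0.02 (SE 0.07), above the EpiLC median by 0.63 (SE 0.19). These SE are over genes and treat the medians as independent, so they do not measure the spread between libraries. Undifferentiated mESCs in the WT EpiLC cultures remain open. Cells with the full mESC profile, at a share within the limits below, could not account for all 19 genes. Cells that kept only part of that profile were not tested. The share of mESCs needed had a median of 7.25% and ran from 1.08% to 30.3% over the 19 genes. The limit was 3.44% from 20 abundant mESC genes, and 15 of the 19 needed more. Klf4 and Prdm14 are among both these 20 and the 19. With the 19 genes left out of the choice of abundant genes, the limit was 4.03%, and 13 needed more. With 50 abundant genes the limit was 8.23%, and 8 of the 19 still needed more. A biological explanation, a faster exit from the naive state with the mutant protein, may also hold and was not tested apart from that.

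Of the genes at least 2-fold changed in mESCs, 86.5% were lower in mutant cells, and 81.8% of those in EpiLCs, a difference that was not tested. EpiLC-like cells in the WT cultures were argued against, since the median gene would need a share of 42.1% and abundant EpiLC genes allowed 3.24%, or 10.1% with 50 genes. Several genes, such as Gm20765 and Gm21293, stood at exactly that median and may share reads. The lower quartile of the shares needed was 23.0%. A trend with GC content, length or expression was argued against as the whole cause, since 79.8% of such genes were lower after its removal (95% interval 75.8 to 83.4) and 86.4% before. This interval is binomial over genes, which are not independent replicates. Other differentiated cells in the WT cultures were not tested, and the genotype itself stays open as the biological explanation. Both may apply, and the WT and mutant lines may differ in other ways.

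In the difference of effects, 1 of 100 drawn splits, the real one, called 1351 genes, and the highest other called 739. For lists it was also 1 of 100, with 14 lists against 12 by the preset correlation. Splits that mix genotypes leave the mutant effect in the spread between libraries, which lowers their counts of genes. The splits thus cannot exclude chance differences between cultures or lines. With an estimated correlation the real split called 3 lists and the highest other also 3, so the number of such lists does not set the real split apart. A split that was not among those drawn, with genotype swapped in EpiLCs only, called 3416 genes and 10 lists, or 7 with an estimated correlation; it tests the sum of both mutant effects, which is a structure of these samples.

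In the other 4 comparisons the 10 splits are too few for a share under 0.05. The real splits called 2574, 2198, 8697 and 9155 genes (mutant against WT in mESCs and EpiLCs, EpiLCs against mESCs in WT and mutant cells), and the highest other called 0 in each. The real splits called 14, 9, 6 and 9 lists, and the highest others 4, 5, 5 and 10, with 3 of 10 splits calling as many in the last. The preset correlation thus called lists in arbitrary splits, while with an estimated correlation the real splits called 8, 6, 5 and 4 lists and the highest other 0. The other splits leave the real difference in the spread between libraries, so a count of 0 genes there was likely in advance. The same spread enters the estimated correlation, so 0 lists there does not show that its calls are sound.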

How the results depend on the processing

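The number of called genes stayed within 1.5 times the reported one under relative log expression size factors, DESeq2, limma-voom, both other filters, a fit to the compared groups and a block on the replicate number, in each comparison where these were run. The labels do not state that replicate numbers pair the samples. With group means removed, libraries of different groups with the same number correlated at r from -0.05 to 0.12. The block gave 2581 (mESCs), 2251 (EpiLCs), 1401 (difference of effects), 8685 (WT) and 9150 (mutant). With 1 library left out the counts were 1948 to 2286, 1665 to 1988, 1133 to 1341, 8114 to 8346 and 8655 to 8815, from fits with fewer libraries. A 2-fold threshold gave 534, 247, 339, 2929 and 3478 genes by construction, and shared calls of 7 higher and 69 lower.

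Lists called with an estimated correlation numbered 8 in mESCs, 3 for the difference and 4 in mutant cells; fry, which does not compare a list with other genes, called 17 in EpiLCs and 25 in WT and 25 in mutant cells. With 1 library left out, 8 to 14 lists were called for the difference. With the block, endoderm in mESCs (0.0502) and general pluripotency (0.0674) and cell cycle (0.062) for the difference were lost with the preset correlation. With an estimated correlation the block ended 5 further calls: general pluripotency in mESCs (0.0505), 2-cell-like genes for the difference (0.0931), and imprinted (0.0569), Hox (0.0569) and oxidative phosphorylation genes (0.0833) in WT cells. Relative log expression size factors ended 1, general pluripotency in mESCs (0.0709). The correlation of the mutant effect with the state change in EpiLCs was 0.31 over genes called in both genotypes, and the cause was not tested.

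Of 5139 alternative values of named genes, 4917 kept direction and call, 215 in 54 genes and comparisons lost the call and 7 changed sign. The 7 are all Epop, which was not called: its log2 fold change ranged from -0.02 to 0.01 in mESCs (0.01 without WT mESC replicate 3), from -0.05 to 0.03 in EpiLCs (0.03 without mutant EpiLC replicate 3) and from -0.04 to 0.04 for the difference (0.00, 0.01 or 0.04). The cause was not tested. Depth limits genes near the floor of 3 counts per group.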

Other observations

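All tests in this part were chosen after the result was seen, and the genes named here were chosen after their values were seen.

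Some genes of the imprinted region around Kcnq1ot1 differed between mutant and WT cells, while others in the region, such as Nap1l4 with log2 fold changes of 0.03 in mESCs and 0.02 in EpiLCs, differed little. Kcnq1ot1, the non-coding RNA that silences neighbours on the paternal allele, fell from 12.7 to 6.16 CPM in mESCs and from 16.3 to 8.52 CPM in EpiLCs (edgeR adjusted p = 3.03e-04 and 6.87e-04), while its neighbours Phlda2 and Slc22a18 rose in both states and Cdkn1c rose in EpiLCs. Cdkn1c in mESCs had a log2 fold change of 0.62 that was not called (edgeR adjusted p = 0.0715). At other imprinted loci, Impact fell by 0.71 and 0.75 on the log2 scale in mESCs and EpiLCs, and Plagl1 by 0.74 and 1.18.

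Counting only tested genes with a mean of at least 2 CPM, the 4 genes of the Y chromosome were higher in mutant cells. Of 415 X-linked genes at that level, 67 were lower and 25 higher in mESCs and 63 lower and 27 higher in EpiLCs. Their medians were -0.06 and -0.03 on the log2 scale. The lower share of X-linked genes was 16.1% in mESCs and 15.2% in EpiLCs. Among autosomes the highest lower share was 15.6% in mESCs, on chromosome 6, and 13.0% in EpiLCs, on chromosome 18. Ddx3y, an RNA helicase, rose from 30.1 to 54.5 CPM in mESCs and from 42.7 to 78.7 CPM in EpiLCs. On the log2 scale Eif2s3y rose by 1.26 and 1.23, Uba1y by 1.30 and 1.03 and Uty, a histone demethylase relative, by 0.93 and 0.85.

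For the Y-linked genes, reads shared with the X-linked copies were argued against, since the summed CPM of these copies changed by 46.3 in mESCs and -17.7 in EpiLCs while the Y genes gained 128.2 and 121.2. A share of WT cells without a Y chromosome would, acting alone, raise all 4 genes by the same fold. All 4 genes were higher, with log2 fold changes from 0.86 to 1.30 in mESCs and from 0.85 to 1.23 in EpiLCs. These folds were unequal, around common values of 1.10 (SE 0.05) in mESCs and 1.05 (SE 0.05) in EpiLCs. Cochran Q, the spread of the folds relative to their errors, was 16.8 and 14.7. Other differences of single genes between the groups can also make the folds unequal, and the errors cover only the spread between libraries. The test thus cannot decide on such a share, which remains open. For Cdkn1c, Phlda2 and Slc22a18, a copy number gain was argued against, since 13 neighbouring genes within 1 Mb had a median log2 fold change of 0.04 in mESCs and 0.14 in EpiLCs. A difference between the WT and mutant cell lines other than EPOP cannot be told apart from the genotype, since 1 cell line label covers the mESC samples and the number of lines per genotype is not given. Loss or gain of imprints or of Y expression in culture may therefore account for these genes as well as the mutant protein, which was not tested.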
